A study of Mus musculus with 4 samples.

How the data were processed

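Single-cell RNA was measured with the 10x Genomics 3' kit, version 3 chemistry, in 4 libraries of sorted mouse embryonic cells, 2 of wild-type (WT) embryos and 2 of embryos lacking the microRNA miR-223 (KO), at embryonic day 10.5. Each library counts as 1 replicate. The labels do not say whether the libraries of a group came from separate embryos or litters, so the p-values measure only the spread between these libraries, which may be partly technical.

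The deposited values are raw UMI counts per gene and cell barcode, per the file headers written by Cell Ranger 3.1.0; a UMI is a molecular tag that marks 1 captured RNA molecule. Seurat 4 is named beside Cell Ranger in the submitters' processing notes, without its role. The deposited count matrices hold barcodes already filtered to cells, per the labels' file list; the aligner settings, genome build and annotation are not given in the sources used here. They hold 31053 genes and 31521 barcodes. Total counts were 95158639 UMIs in WT replicate 1, 181682389 in WT replicate 2, 109713066 in KO replicate 1 and 167542930 in KO replicate 2. Intervals on shares and counts, and floors for groups without a UMI, cover counting error only.

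Cells with at least 1000 genes and under 10% mitochondrial UMIs were kept. Doublets were scored against simulated doublets (2 per cell) among cells with under 20% mitochondrial UMIs. The highest-scoring cells of each library were called at the rate expected of the kit, 0.8% per 1000 barcodes. That is 3.13%, 8.95%, 4.90% and 8.24% of this wider pool in WT replicates 1 and 2 and KO replicates 1 and 2. Of the cells under 10%, 3.61%, 10.1%, 5.30% and 8.90% were removed in the same order. The remaining 19172 cells were normalised to 10000 UMIs and log-transformed. The 2000 variable genes were chosen by their mean rank of dispersion within each library. Each gene was then centred and scaled within each library, which takes out mean differences between libraries and depends on the cells each library holds. On these values 40 principal components and a graph of 20 nearest neighbours were used for Leiden clustering at resolution 1. No other batch correction was made. The 24 clusters were named "X-like" from fixed marker genes, with at least 3 detected markers per name. The minimum number of genes per cell was set once the counts were in hand, and the limits on the marker folds (a mean log2 fold of 1.5, or 0.5 among endothelial clusters) were set after seeing the clusters. Clusters whose leading genes went against a name stayed unnamed; they hold 5.14%, 8.33%, 6.93% and 7.42% of the cells of the 4 libraries in the same order.

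UMI counts were summed per library and class and tested across the 4 libraries with edgeR 4.0.16 (quasi-likelihood fit, robust, filterByExpr, TMM scaling) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Cells were never used as replicates in these tests. A class was tested where each library held at least 20 of its cells. The hemogenic endothelial-like class has 11 cells in WT replicate 1 and was tested with a minimum of 10 cells, a choice made after seeing the data. The 29 gene lists were tested with camera of limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. With 2 libraries per group the estimated form can hardly pass, and it was not run on simulated counts. A list that fails it is therefore not shown to be unchanged, nor is a list that passes only the preset form shown to have changed. Shares of cells were compared by an exact two-sided permutation test, which with 2 libraries against 2 cannot give a p below 0.33. To compare the share of cells with a UMI of Runx1 or another single gene, each cell was thinned at random to 5000 UMIs, in 1 draw per comparison, and shallower cells were left out. Intervals on shares are exact binomial (Clopper-Pearson) at 95%. Python 3.11.15 with scipy 1.17.1, igraph 0.11.9 and leidenalg 0.10.2 was used for the cells.

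Gene positions and 3' UTRs come from GENCODE release M21 (mouse build GRCm38), a copy whose build may differ from the authors'. It was matched by gene identifier, for 30934 of the 31053 genes. A gene was taken to carry a miR-223 site where an annotated 3' UTR holds AACTGAC or AACTGACA, the match to positions 2 to 8 of the microRNA without or with the following A.

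The groups, tests, marker genes, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Gene tests in liver sinusoidal or lymphatic-like, sprouting-like, primordial germ cell-like and mesenchymal-like cells were not among the fixed tests. The genes named are, per class, up to 10 higher and 10 lower genes with the smallest adjusted p whose KO libraries both lie beyond both WT libraries, up to 4 passing members of each list, and 17 genes given whatever their test. Where fewer than 3 genes pass in a direction, the 3 with the smallest raw p are given as values. Of the 15 genes called in endothelial-like cells, 1 is not reported here by name. A fold against a group without a UMI is a lower bound computed with a floor of 3 UMIs over the group.

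Each fit was tested on simulated counts drawn from the means and library sizes of the same libraries. With 100 genes changed by 1 and 100 by 2 on the log2 scale, it recovered 75% and 96% in endothelial-like cells (14534 genes), 71% and 97% in arterial-like cells (11568 genes), 70% and 97% in venous-like cells (11433 genes), 46% and 90% in hemogenic endothelial-like cells (9255 genes), and 68% and 88% for the interaction of genotype and class (12059 genes). Genes simulated without a change made up 13 of 184, 9 of 177, 4 of 171, 5 of 141 and 7 of 163 calls in the same order. Alternatives covered the scaling, the filter on low counts, DESeq2 1.42.0 in place of edgeR, doublets kept, a mitochondrial limit of 20%, thinning to equal depth, hemoglobin genes left out, cluster resolutions of 0.5 and 2, the replicate number as a block, and each library left out in turn.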

Results

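Single-cell RNA profiles were taken from the aorta-gonad-mesonephros (AGM) region of mouse embryos at embryonic day 10.5, where the first blood stem cells arise from the wall of the aorta. Cells bearing the endothelial surface protein CD31 and lacking the blood cell protein CD45 were sorted. There were 2 libraries of wild-type (WT) embryos and 2 of embryos lacking miR-223 (KO), a microRNA abundant in myeloid blood cells. The libraries held 3917 and 11186 barcodes in WT replicates 1 and 2, and 6119 and 10299 in KO replicates 1 and 2. After the filters, 2295, 6877, 4126 and 5874 cells remained in the same order, with medians of 30152, 18205, 20147 and 18675 UMIs per cell.

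Most cells were endothelial-like, with 73.1% and 83.9% of the cells in the WT libraries and 70.0% and 82.5% in the KO libraries (exact permutation p = 0.667). Arterial-like cells, in cluster 5 led by Gja4, Gja5 and Hey1 and in cluster 11 by Htra1, Tmem100 and Gja5, made up 8.37% and 12.7% in WT and 10.3% and 12.3% in KO (exact p = 1). Venous-like cells, whose top 10 genes hold 1 venous marker (Nrp2), 1 sinusoidal or lymphatic marker (Prox1) and 1 hemogenic marker (Bmp4), made up 9.15% and 9.76% in WT and 7.90% and 10.1% in KO (exact p = 1). Cells like liver sinusoidal or lymphatic endothelium, led by Oit3, Lyve1 and Stab2, were 6.53% ± 1.42 in WT and 4.33% ± 0.0603 in KO (SD, n = 2 each, exact permutation p = 0.33). Sprouting-like cells were 6.75% and 7.24% in WT and 4.41% and 6.50% in KO (exact p = 0.33). Clusters 0, 7 and 8, whose sprouting markers lay under a limit set after seeing the data, together held 19.7%, 22.5%, 17.7% and 22.5% of the cells of WT replicates 1 and 2 and KO replicates 1 and 2. Clusters 7 and 8 also lacked sprouting markers among their top 10 genes within the endothelium, so the limit alone did not keep them out. Primordial germ cell-like cells were 2.004% and 2.12% in WT and 2.16% and 2.52% in KO. Mesenchymal-like cells, which the sort selects against, were 14.7% in WT replicate 1 and 12.7% in KO replicate 1, but 3.48% in WT replicate 2 and 4.39% in KO replicate 2. With 2 libraries against 2, no exact test of a share can pass 0.05; the smallest possible p is 0.33. The sort sets these shares in part, and no cluster earned a myeloid-like or a hematopoietic progenitor-like name.

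The host transcript of miR-223, F630028O10Rik, was higher in both KO libraries. Its 2 annotated transcripts span chromosome X from 96239926 to 96243636 on the plus strand (GRCm38, GENCODE M21), and the miR-223 hairpin lies at 96242817 to 96242926 inside an exon of each. Over all barcodes it had 0.105 and 0.330 CPM (UMIs scaled to equal library totals) in WT replicates 1 and 2, and 2.37 and 3.90 in KO replicates 1 and 2. It was most abundant in megakaryocyte-like cells, with 5.17 and 34.9 CPM in WT and 166 and 283 in KO, and reached 2.70 and 10.3 in WT and 38.1 and 58.1 in KO in hemogenic endothelial-like cells. In endothelial-like cells it rose by 4.84 on the log2 scale (SE 0.607, edgeR adjusted p = 0.0388), from 0 and 4 UMIs to 40 and 72; this call was lost with doublets kept. The extent of the deletion is not given in the sources used here. A 3' tag that lies outside the deleted part checks nothing about the label of a library, so these values neither check the genotypes nor measure the microRNA.

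**Figure D1:**
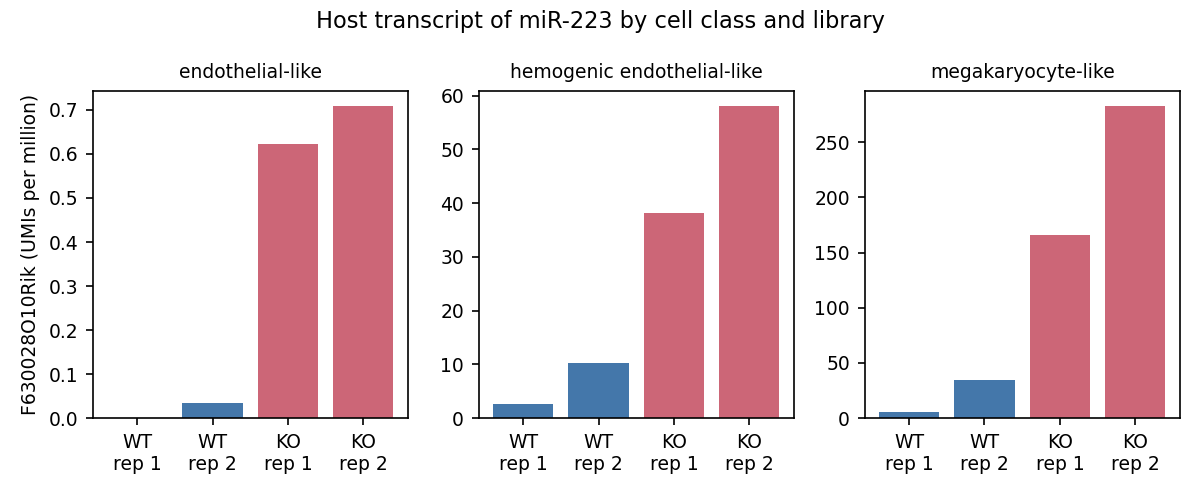
Bars give F630028O10Rik CPM in endothelial-like, hemogenic endothelial-like and megakaryocyte-like cells of each library, 2 WT and 2 KO. Both KO libraries lie above both WT libraries in each class, up to 283 CPM in the megakaryocyte-like cells of KO replicate 2.

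The title of the series names hemogenic endothelium, the endothelial cells that turn into blood cells. Hemogenic endothelial-like cells, led by Spi1, Runx1, Ikzf2, Nupr1 and Adgrg1, had 5 hemogenic, 4 hematopoietic progenitor and 1 myeloid marker among their top 10 genes. The name therefore does not part hemogenic endothelium from early blood cells. These cells were 0.479% (95% exact interval 0.240 to 0.856) of the cells in WT replicate 1 and 1.12% (0.885 to 1.40) in WT replicate 2. They were 3.32% (2.79 to 3.91) in KO replicate 1 and 1.36% (1.08 to 1.69) in KO replicate 2. The mean was 0.799% ± 0.453 in WT and 2.34% ± 1.38 in KO (SD, n = 2 each), a difference of 1.54 percentage points that the exact permutation test cannot separate from chance (p = 0.33). The interval of KO replicate 2 overlaps that of WT replicate 2 and lies above that of WT replicate 1. The difference was 0.562 without KO replicate 1, which has almost no cells with Xist, 2.52 without KO replicate 2, 1.22 without WT replicate 1 and 1.86 without WT replicate 2. Arterial-like cluster 11, whose hemogenic markers lay under a limit set after seeing the data and did not lead it, held 2.14%, 3.88%, 4.65% and 4.15% of the cells of WT replicates 1 and 2 and KO replicates 1 and 2. Among endothelial-like and hematopoietic-like cells only, the shares were 0.623%, 1.31%, 4.41% and 1.60% in WT replicates 1 and 2 and KO replicates 1 and 2.

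**Figure D2:**
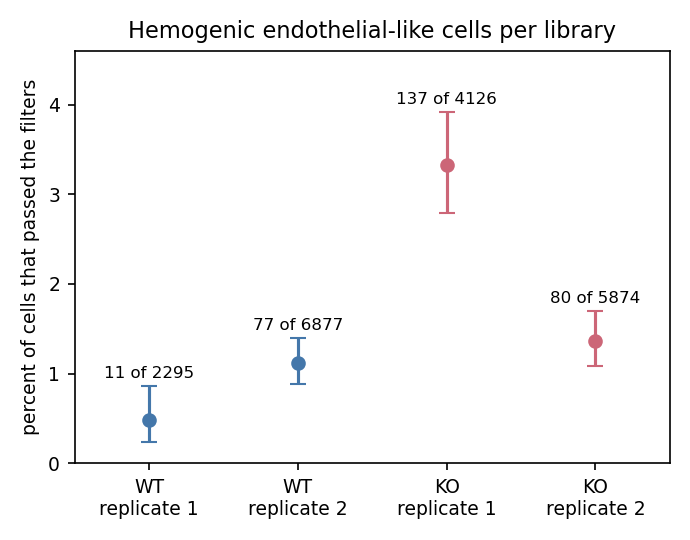
Points give the percent of cells in each library that were hemogenic endothelial-like, with 95% exact binomial intervals for counting error and the number of such cells. KO replicate 1 lies at 3.32%, and the interval of KO replicate 2 overlaps that of WT replicate 2 and lies above that of WT replicate 1.

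Runx1, the transcription factor needed for blood formation from endothelium, was detected in few endothelial-like cells, a class that leaves out the hemogenic endothelial-like cluster, which Runx1 helps to define. At 5000 UMIs per cell, 9 of 1662 cells (0.542%) had a Runx1 UMI in WT replicate 1, 46 of 5717 (0.805%) in WT replicate 2, 19 of 2870 (0.662%) in KO replicate 1 and 39 of 4790 (0.814%) in KO replicate 2. The difference of 0.0650 percentage points was below the spread between libraries (exact permutation p = 0.667). These shares come from 1 random thinning. Another draw, with doublets kept, gave 0.464% and 0.688% in WT and 0.659% and 0.512% in KO. In KO replicate 2 that was 27 of 5272 cells, so the shares also vary between draws, which their intervals do not cover. Between 15 and 56 shallower cells per library were left out, and the median depth before thinning was 31107, 18751, 20553 and 19191 UMIs. Without thinning the shares were 3.46%, 2.84%, 2.56% and 2.91%. With hemogenic endothelial-like cells included, a choice made after seeing the data, the shares at 5000 UMIs were 0.956% and 1.57% in WT and 3.03% and 1.73% in KO, a difference of 1.11 percentage points (exact permutation p = 0.33). In primordial germ cell-like cells, which should lack Runx1, 0 of 45, 142, 88 and 146 cells had a UMI, which allows shares of up to 7.87%, 2.56%, 4.11% and 2.495% (exact binomial), at medians of 57499, 42183, 36470 and 41513 UMIs. Without thinning, 0 of 46, 1 of 146 (0.685%), 2 of 89 (2.25%) and 3 of 148 (2.03%) of them had one. These germ cell-like counts are too few to set a background for the endothelial-like shares. In mesenchymal-like cells, part of which is known to express Runx1 around the aorta, the share was 1.19%, 3.004%, 1.54% and 2.41% at medians of 25113, 18363, 18817 and 17219 UMIs. In hemogenic endothelial-like cells the thinned share was 45.5% and 55.3% in WT and 59.6% and 48.1% in KO.

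In endothelial-like cells, 7 genes rose and 8 fell in KO among 14534 tested (edgeR quasi-likelihood, adjusted p under 0.05), and 85 and 157 had an unadjusted p under 0.05. Wdfy1, an endosomal protein that binds a membrane phospholipid, rose by 2.42 on the log2 scale (SE 0.139, edgeR adjusted p = 0.000739), from 9.81 ± 0.151 to 52.5 ± 0.698 CPM (SD, n = 2 each). Npw, which encodes neuropeptide W, rose by 5.54 (SE 0.349), and Cacna1e, a voltage-gated calcium channel subunit, by 2.20 (SE 0.214). Tagap, a GTPase-activating protein of T cells, had no UMI in WT and 40 and 48 in KO, at least 31.3-fold higher with a floor of 3 UMIs over the group. The serine protease gene Prss41 rose by 3.68 (SE 0.448), and the antisense transcript Gm26873 by 4.85 (SE 0.511).

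Mxra7, a gene linked to matrix remodelling, fell by 2.12 in endothelial-like cells (SE 0.133, edgeR adjusted p = 0.000739), from 67.8 ± 0.473 to 15.6 ± 0.169 CPM (SD, n = 2 each). The small GTPase gene Arl11 fell by 4.41 (SE 0.376), the zinc finger gene Zfp945 by 1.44 (SE 0.174) and the antisense transcript AC122413.1 by 2.80 (SE 0.304). Gm10642, which overlaps Mindy2 on the other strand, fell by 3.98 (SE 0.402). Gm16867 had 73 and 289 UMIs in WT and 2 and 0 in KO, a ratio of 169.5 (95% counting interval 46.6 to 1405). Rnaset2b, a ribonuclease gene, fell by 3.32 (SE 0.199), but is uncertain because it has a near-identical copy, Rnaset2a, which had a log2 change of 0.28 (edgeR adjusted p = 0.9999). Of the 15 called genes, 9 overlap another annotated gene, 1 of them on the same strand, and the strand setting of the counting is not given in the sources used here. In all, 7 of the 15 lie on chromosome 17 between 6948446 and 24658457 (GRCm38). Leaving out WT replicate 1, WT replicate 2 or KO replicate 2 raised the count to 36, 48 and 64 genes. Without KO replicate 1 there were 18, and Zfp945 no longer passed. With doublets kept Tagap, Zfp945 and Prss41 did not pass, nor did Tagap and Prss41 with sums thinned to equal depth.

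**Figure D3:**
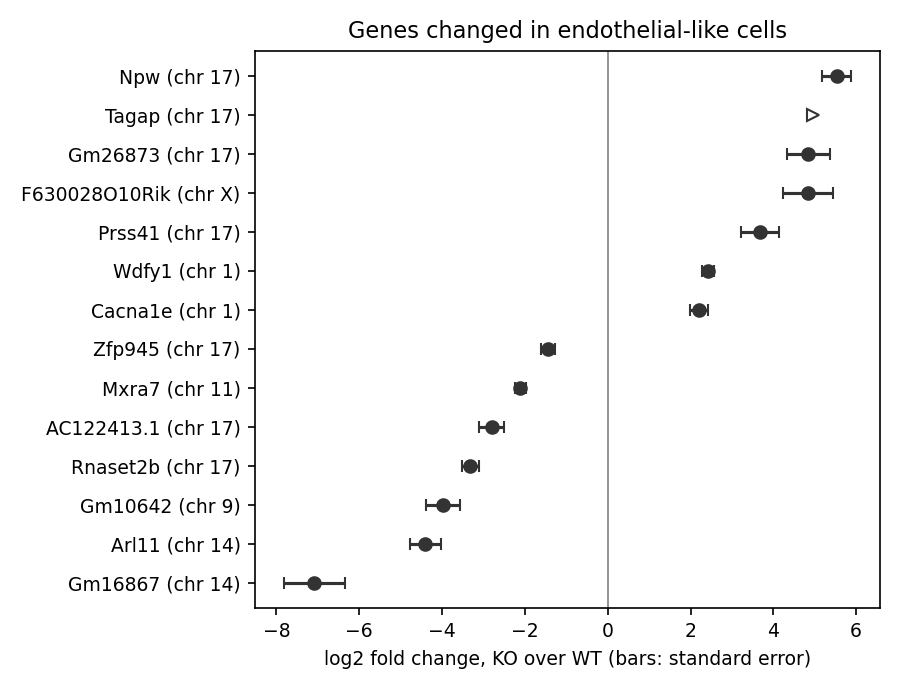
Points give the log2 fold change, KO over WT, of 14 of the 15 genes called in endothelial-like cells with 1 standard error, and each gene's chromosome; the triangle marks Tagap at its lower bound. The changes run from Wdfy1, Npw and Cacna1e above 0 to Mxra7, Arl11 and Rnaset2b below it, and 7 of the genes drawn are on chromosome 17.

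Genes that mark hemogenic and blood cells did not pass in endothelial-like cells, a class that leaves out the hemogenic endothelial-like cluster. Runx1 had a log2 change of 0.13 (SE 0.250), from 1.31 ± 0.237 to 1.44 ± 0.129 CPM (SD, n = 2 each, edgeR adjusted p = 0.9999). The log2 changes, none of which passed, were 0.78 for Gfi1, 0.03 for Gata2, -0.15 for Kit, 0.31 for Myb, -0.16 for Itga2b, 0.46 for Spi1, 0.38 for Cd44 and 0.31 for Mpo. For genes described before as miR-223 targets they were 0.12 for Alg2, 0.06 for St3gal2 and -0.05 for Mef2c. Ptprc (1, 0, 1 and 2 UMIs) and Csf1r (5, 9, 3 and 10) were too rare to test. Xist had a log2 change of -1.003 (SE 3.15), because KO replicate 1 had 1 UMI, and the Y-linked Ddx3y 0.22. Xist was seen in 50.9% and 43.8% of endothelial-like cells in WT and 0.0346% and 43.9% in KO.

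Among 29 gene lists in endothelial-like cells, 4 passed with camera at a preset correlation, and 0 members of these lists passed over all genes (edgeR). Of the 14 genes tested in the NF-kB and inflammatory list, 11 had lower point estimates (camera adjusted p = 0.00169, against adjusted p = 0.930 with an estimated correlation). The estimated form can hardly pass with 2 libraries per group, so here and below it does not decide for or against a list. Adjusted over the list alone (edgeR), 2 of its members passed, the chemokine Cxcl1 (-2.46, adjusted p = 0.00322) and the adhesion molecule Vcam1 (-0.98, adjusted p = 0.0137), which did not pass without WT replicate 1 (0.0586) or KO replicate 1 (0.0675). In the list of dissociation and immediate early genes 15 of 22 were lower (adjusted p = 0.192), among them Btg2, with 98.9 and 48.9 CPM in WT and 39.7 and 39.9 in KO. That list passed as lower without WT replicate 2 (adjusted p = 1.07e-14) or KO replicate 1 (0.000126), and as higher without WT replicate 1 (0.00015). The macrophage list had 5 tested genes, 4 of them lower (adjusted p = 0.0123; adjusted p = 0.930 with an estimated correlation), and 1 passed adjusted over the list alone, Mrc1 (-0.91, adjusted p = 0.00829, and 0.0969 without KO replicate 1), which sinusoidal endothelium also expresses. Cells like liver sinusoidal or lymphatic endothelium, with Mrc1 among their leading genes, were 173 of 1677 and 380 of 5771 endothelial-like cells in WT. In KO they were 177 of 2887 and 257 of 4846. In the mesenchymal list 10 of 14 were higher (adjusted p = 0.0130, and adjusted p = 0.930 with an estimated correlation), and 1 passed adjusted over the list alone, the smooth muscle actin Acta2 (1.32, adjusted p = 0.000991). Mesenchymal-like cells were 14.7% and 3.48% of the WT libraries and 12.7% and 4.39% of the KO libraries. The cholesterol synthesis list had 17 of 19 higher (adjusted p = 0.0132; adjusted p = 0.930 with an estimated correlation) and 0 that passed adjusted over the list alone. The NF-kB list no longer passed without WT replicate 1 (adjusted p = 0.576), the macrophage list without WT replicate 1 (0.204) or KO replicate 1 (0.415), the mesenchymal list without WT replicate 2 (0.930) or KO replicate 1 (0.704), and the cholesterol list without WT replicate 2 (0.278) or KO replicate 1 (0.952). With doublets kept the macrophage (0.0672) and mesenchymal (0.0654) lists did not pass, nor did the macrophage list without a filter on low counts (0.147) or the mesenchymal list without genes near called genes (0.121).

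The other 25 lists did not pass in endothelial-like cells, with camera adjusted p from 0.0970 to 0.956. Of 29 described miR-223 targets, 13 were higher and 16 lower (median log2 change -0.02, adjusted p = 0.792). The hemogenic endothelium list had 13 of 20 higher (adjusted p = 0.684), the hematopoietic progenitor list 8 of 16 (0.846) and the myeloid list 6 of 12 (0.568), in which Mrc1 passed adjusted over the list alone (edgeR adjusted p = 0.0199, and 0.182 without KO replicate 1). The N-glycan precursor list had 23 of 38 higher (0.149), and N-glycan processing 24 of 39 (0.568). The remaining lists were arterial and venous identity, pan-endothelial, lymphoid, megakaryocyte, erythroid, nephric or coelomic epithelial, primordial germ cell, endothelial-to-mesenchymal change, Notch signalling, interferon, both cell cycle lists, glycolysis, oxidative phosphorylation, unfolded protein response, mitochondrially encoded genes and embryo sex markers.

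Genes with a miR-223 seed site in an annotated 3' UTR, which the microRNA could repress, did not move as a group in endothelial-like cells. The median log2 change was -0.00303 over 1498 genes with a site and -0.00119 over 11724 without (limma's camera on this 1 set, adjusted p = 0.831, and adjusted p = 0.730 with an estimated correlation). The direction turned, still without passing in limma's camera, when WT replicate 2 (adjusted p = 0.142) or KO replicate 1 (adjusted p = 0.635) was left out. In hemogenic endothelial-like cells 1068 genes had a seed site (limma's camera, adjusted p = 0.473).

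In arterial-like cells 2 genes rose and 2 fell among 11568 tested (edgeR), and 113 and 139 had an unadjusted p under 0.05. Wdfy1 rose by 2.25 (SE 0.182, edgeR adjusted p = 0.000588). Npw rose from 1 and 2 UMIs in WT to 24 and 56 in KO, a ratio of 25.97 (95% counting interval 8.57 to 129). Rnaset2b fell by 2.98 (SE 0.343) and Mxra7 by 1.64 (SE 0.183, edgeR adjusted p = 0.00782 for both). Acta2, with a log2 change of 1.16 (SE 0.179), and the methyltransferase gene Mettl23, with -1.01, did not pass (adjusted p = 0.0828 for both). All 24 DNA replication genes of the S phase list had higher point estimates (median 0.44, camera adjusted p = 1.74e-13, against adjusted p = 0.851 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. KO replicate 1 stood apart in the list: Rrm2 had 30.6 and 26.1 CPM in WT and 64.3 and 29.0 in KO, and Cdt1 14.6 and 12.4 in WT and 27.0 and 16.3 in KO. Without KO replicate 1 the S phase list did not pass (camera adjusted p = 0.193). The NF-kB list was lower (11 of 12 genes, adjusted p = 0.000467), and the mesenchymal and unfolded protein response lists were higher (adjusted p = 0.0319 for both). All 3 had adjusted p = 0.851 with an estimated correlation. The median log2 change of the NF-kB list was -0.273, against -0.0954 without WT replicate 1 and -0.249 without WT replicate 2. It was -0.245 without KO replicate 1 and -0.364 without KO replicate 2. The mesenchymal list did not pass without WT replicate 1 (adjusted p = 0.0563), WT replicate 2 (0.0548), KO replicate 1 (0.209) or genes near called genes (0.372), nor the unfolded protein response list without WT replicate 2 (0.591) or KO replicate 1 (0.717). Adjusted over the list alone (edgeR), Acta2 (adjusted p = 0.000361), Tagln (0.55, adjusted p = 0.0435) and Cxcl1 (-2.87, adjusted p = 0.00613) passed, and 0 list members passed over all genes. Tagln did not pass without WT replicate 2 (edgeR adjusted p = 0.149) or KO replicate 1 (0.419), nor Cxcl1 without WT replicate 2 (0.119). Cluster 11, which has Acta2 among its leading genes within the endothelium, was 25.5% and 30.7% of arterial-like cells in WT and 45.2% and 33.9% in KO. Acta2 had 93.2 and 76.2 CPM in WT and 97.7 and 181 in KO in that cluster, and 8.33 and 4.31 in WT and 31.4 and 3.27 in KO in cluster 5, the rest of the class. Runx1 (0.75, SE 0.573) and Gfi1 (0.27, SE 0.581) did not pass. With sums thinned to equal depth Npw and Rnaset2b did not pass. The number of genes rose to 13, 15, 11 and 74 without WT replicates 1 and 2 and KO replicates 1 and 2.

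In venous-like cells 2 genes rose and 9 fell among 11433 tested (edgeR), and 74 and 148 had an unadjusted p under 0.05. Wdfy1 rose by 2.30 (SE 0.191, edgeR adjusted p = 5.57e-05), and Npw, absent in WT, was at least 16.5-fold higher. Rnaset2b fell by 3.15 (SE 0.347), Mxra7 by 1.54 (SE 0.185), Zfp945 by 1.40 (SE 0.210), the insulin-degrading enzyme Ide by 1.15 (SE 0.171), the deubiquitinase Mindy2 by 1.30 (SE 0.207) and Mettl23 by 1.01 (SE 0.160). Arl11 had 48 UMIs in WT and 1 in KO, a ratio of 45.5 (95% counting interval 7.79 to 1835), and Gm16867 was at least 14.5-fold lower. The ribosomal protein gene Rps2 fell by 0.82 (SE 0.133, edgeR adjusted p = 0.0219), from 6565 ± 453 to 3717 ± 239 CPM (SD, n = 2 each), and is uncertain because ribosomal protein genes have many pseudogenes. It starts at 24718116 on chromosome 17 (GRCm38), near the called gene Npw at 24657330. It was also called lower in cells like liver sinusoidal or lymphatic endothelium (-0.89) and in primordial germ cell-like cells (-0.88). The arterial identity (15 of 17 genes) and Notch (11 of 12) lists were lower in venous-like cells (camera adjusted p = 2.24e-05 and 2.98e-05). Their sizes depended on single libraries. The median log2 change of the Notch list was -0.362, against -0.183 without WT replicate 1, -0.498 without WT replicate 2, -0.174 without KO replicate 1 and -0.332 without KO replicate 2. For arterial identity it was -0.232, against -0.251, -0.292, -0.140 and -0.321 in the same order. The S phase list (22 of 24), the G2 and M phase list (25 of 25), the macrophage list (3 of 3) and the cholesterol list (14 of 19) were higher (adjusted p = 2.98e-05, 2.98e-05, 0.00635 and 0.0478). All 6 had adjusted p = 0.821 with an estimated correlation. KO replicate 1 stood apart in the cell cycle lists, with Ccnb1 at 28.5 and 28.2 CPM in WT and 54.7 and 29.7 in KO. Without it the S phase (adjusted p = 0.848) and cholesterol (0.955) lists did not pass, and the G2 and M phase list turned downward (0.711). Without WT replicate 2 the S phase (0.0676), cholesterol (0.247) and macrophage (0.247) lists did not pass, nor did the macrophage list without KO replicate 2 (0.301) or the cholesterol list without genes near called genes (0.0648). Adjusted over the list alone (edgeR), Sox18 (-0.71, adjusted p = 0.0337) and Twist1 (1.71, adjusted p = 0.0147) passed, and 0 list members passed over all genes. Twist1 had 2.46 and 1.93 CPM in WT and 11.05 and 3.83 in KO, and without KO replicate 1 its log2 change was 0.84 (SE 0.449, edgeR adjusted p = 0.555). It also did not pass without WT replicate 1 (0.175) or WT replicate 2 (0.281), nor did Sox18 without WT replicate 1 (-0.37, adjusted p = 0.952), KO replicate 1 (0.0545) or KO replicate 2 (0.0568). Runx1 had a log2 change of -0.07 (SE 0.439) and did not pass. Arl11 and Gm16867 did not pass with DESeq2 or with doublets kept, nor did they, Mindy2 and Npw with thinned sums. The number of genes was 20, 17 and 48 without WT replicate 2, KO replicate 1 and KO replicate 2; Arl11 and Gm16867 were not tested without WT replicate 2, nor Npw without KO replicate 2.

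In hemogenic endothelial-like cells, tested although WT replicate 1 held 11 of them, 2 genes rose and 1 fell among 9255 (edgeR), and 140 and 150 had an unadjusted p under 0.05. Wdfy1 rose by 2.23 (SE 0.311, edgeR adjusted p = 0.00360) and F630028O10Rik by 2.41 (SE 0.388, edgeR adjusted p = 0.0155), and Rps2 fell by 0.90 (SE 0.148, edgeR adjusted p = 0.0155). Rps2 is as uncertain here as in venous-like cells. The log2 changes of blood and hemogenic genes did not pass (edgeR adjusted p = 0.9998): 0.15 for Runx1, 0.24 for Gfi1, -0.19 for Gata2, -0.41 for Kit, -0.04 for Myb, -0.11 for Spi1, 0.30 for Cd44, -0.13 for Itga2b and 0.61 for the myeloid granule enzyme Mpo. Spi1, Runx1, Gfi1 and Myb are among the top 10 genes that set this class apart. Their levels within it therefore say little about whether the KO changes them. Ptprc, which encodes CD45, had 18.5 and 20.2 CPM in WT and 5.51 and 15.4 in KO (log2 change -1.03, SE 0.451, edgeR adjusted p = 0.9998). The LIM domain gene Crip2, with a log2 change of 1.003 (SE 0.192, edgeR adjusted p = 0.0763), Mettl23 and Ide did not pass. F630028O10Rik did not pass with DESeq2, with doublets kept or with a mitochondrial limit of 20%, Wdfy1 with DESeq2, or Rps2 with that limit. The count was 44, 20 and 15 without WT replicate 2, KO replicate 1 and KO replicate 2; Wdfy1 was lost without WT replicate 2, and Rps2 without either KO library.

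Of 27 lists in hemogenic endothelial-like cells, 6 passed with camera at a preset correlation, and 0 passed with an estimated correlation. The S phase list was higher (22 of 24 genes, adjusted p = 1.54e-07, and adjusted p = 0.781 with an estimated correlation), and the hematopoietic progenitor list lower (18 of 21, adjusted p = 6.08e-05, and adjusted p = 0.787 with an estimated correlation). The pan-endothelial (20 of 22), arterial identity (17 of 19) and unfolded protein response (12 of 14) lists were higher, with adjusted p = 0.000448, 0.000744 and 0.0425, and the interferon list was lower (10 of 13, adjusted p = 0.0308); with an estimated correlation these had adjusted p = 0.781 or, for interferon, adjusted p = 0.787. The hematopoietic progenitor list turned upward without WT replicate 2 (adjusted p = 0.469) or KO replicate 1 (0.823), and the interferon list without KO replicate 1 (0.847); it also lost its call without WT replicate 2 (0.660). The arterial identity list lost it without WT replicate 1 (0.101) or KO replicate 2 (0.117), the pan-endothelial list without WT replicate 1 (0.101), and the unfolded protein response list without WT replicate 1 (0.101), WT replicate 2 (0.0918) or KO replicate 1 (0.307). With doublets kept the arterial identity (adjusted p = 0.172), pan-endothelial (0.181), interferon (0.461) and unfolded protein response (0.368) lists did not pass. Adjusted over the list alone (edgeR), the immediate early genes Klf4 (-1.06), Jun (-0.57) and Klf2 (-0.60) passed (adjusted p = 0.0398 each), as did the Y-linked Eif2s3y (1.12), Uty (1.47) and Ddx3y (0.80), and 0 list members passed over all genes. Klf4, Jun and Klf2 did not pass without WT replicate 1 (edgeR adjusted p = 0.0875, 0.270 and 0.194) or KO replicate 1 (0.319, 0.0972 and 0.315), nor Jun without KO replicate 2 (0.0953). Eif2s3y, Uty and Ddx3y did not pass without WT replicate 2 (edgeR adjusted p = 0.510, 0.510 and 0.154) or KO replicate 1 (0.354 each), nor Ddx3y without WT replicate 1 (0.0538). The hemogenic endothelium list, which holds genes that set this class apart, had 11 of 21 genes higher (camera adjusted p = 0.853).

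Whether the KO effect differed between arterial-like and venous-like cells was tested for 12059 genes, and 1 passed. Pf4, a platelet chemokine, had a log2 ratio of folds of -1.97 (SE 0.284, edgeR adjusted p = 0.00302), which was -3.07 without KO replicate 2. It had 9.11 and 12.7 CPM in arterial-like cells of WT and 1.18 and 11.3 in KO, and 4.89 and 5.72 in venous-like cells of WT and 4.79 and 18.9 in KO. Over all barcodes Pf4 had 112 and 92.0 CPM in WT and 35.1 and 171 in KO, and megakaryocyte-like cells, which it marks, were 1.31% and 0.364% of the cells in WT and 0.364% and 0.749% in KO. The change within either class did not pass, with 434 genes at an unadjusted p under 0.05 for the interaction, and DESeq2 called 0 genes (26 unadjusted). Pf4 did not pass with a mitochondrial limit of 20% or with thinned sums either. The number of genes was 3, 38, 2 and 64 without WT replicates 1 and 2 and KO replicates 1 and 2.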

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

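The tests of the sort gate, of the dissected tissue, of gene positions and of F630028O10Rik were chosen only after the result was seen. The test of seed sites among the called genes was chosen before. The tests of embryo sex are built on the library with almost no Xist, its hemogenic endothelial-like share and the called genes. Their form was therefore set after these results were seen.

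The KO effect on Pf4, a platelet chemokine, differed between arterial-like and venous-like cells, with a log2 ratio of folds of -1.97 (edgeR adjusted p = 0.00302), while the change in either class did not pass (log2 -0.69, SE 0.814, and 1.23, SE 0.569); Pf4 was called without any 1 library (log2 ratio -3.07 without KO replicate 2) but not with DESeq2, a mitochondrial limit of 20% or thinned sums, and over all barcodes Pf4 had 112 and 92.0 CPM in WT and 35.1 and 171 in KO.

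KO replicate 1 had the highest share of hemogenic endothelial-like cells, 3.32%, and almost no cells with Xist. In the other 3 libraries pooled, cells with Y-linked UMIs were hemogenic endothelial-like less often than cells with Xist UMIs (0.927% of 7011 against 1.54% of 5463, ratio 0.603, 95% interval 0.437 to 0.832). The shares were 0.298% against 0.735% in WT replicate 1 and 0.824% against 1.75% in WT replicate 2. In KO replicate 2 they were 1.28% against 1.66%. These values argue against more male cells as the source. The interval takes cells as independent, however, and the number of embryos per library is not given. Cells with CD45 that passed the gate would raise Ptprc, but it had 5.50 CPM in this class of KO replicate 1 (3.20 to 8.80) against 17.4 in the others pooled. More aortic tissue would raise arterial-like cells too, and their whole share was 0.929 times the mean of the other libraries (upper bound 1.02, for counting error only) against 3.36 times for the hemogenic endothelial-like share, but 1 arterial-like cluster at resolution 2, led by Tmem100, Gja5 and Nkx2-3, held 2.96% (2.46 to 3.52) against 1.05%, 1.31% and 1.94%. KO replicate 1 also stood apart in its neural-like or neural crest-like cells, with 81 and 37 of its 4126 cells in clusters 19 and 23. These clusters held 19 and 10 of 2295 cells in WT replicate 1 and 28 and 5 of 6877 in WT replicate 2. In KO replicate 2 they held 42 and 1 of 5874. So aortic tissue, embryo stage, litter and the genotype stay open. The interval of KO replicate 2 (1.08 to 1.69) lies above that of WT replicate 1 (0.240 to 0.856) and overlaps that of WT replicate 2 (0.885 to 1.40), so whether it shares part of the excess is open too.

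The genes changed in endothelial-like cells lie close together. Among the 15 genes, 7 pairs were within 5 Mb of each other against 0.591 in random draws of tested genes (permutation p = 0.0001, the smallest 10000 draws can give), and 7 were on chromosome 17 where 0.714 were expected. In primordial germ cell-like cells all 6 of them that were tested had the same sign and an unadjusted p under 0.05 (3 called, edgeR), and in mesenchymal-like cells all 6 tested had the same sign, 5 of them with an unadjusted p under 0.05 (1 called), so segments from another mouse strain carried by one of the lines are a candidate explanation, with no genotypes to test it. The sex of KO replicate 1 does not account for them, since without it 15 of 15 kept their direction and at least 0.75 of their log2 change. Loss of repression by miR-223 stays open for single genes: of 5 higher genes with an annotated 3' UTR, 1 has a seed site (exact hypergeometric p = 0.452), and in the fit over all 14534 genes the median log2 change of genes with a site lies -0.00194 from that of genes without (95% bootstrap interval -0.00855 to 0.00474).

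F630028O10Rik, the host transcript of miR-223, was higher in both KO libraries. Within hemogenic endothelial-like cells the lower KO library had 3.69 times the higher WT library. More hemogenic or megakaryocyte-like cells, or free RNA from them, therefore do not account for the difference in that class. In endothelial-like cells the KO libraries had 0.622 and 0.709 CPM, below their 2.37 and 3.90 over all barcodes. Free RNA was not tested there and stays open for the endothelial-like call. Lack of a second X chromosome in KO replicate 1 does not account for the difference in hemogenic endothelial-like cells. There KO replicate 2, with cells of both sexes, had 5.61 times the higher WT library. A transcript altered by the targeted allele and lost feedback by the microRNA both stay open and were not tested, because counts per gene do not hold the place of the tags in the locus.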

How the results depend on the processing

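The alternatives for hemogenic endothelial-like genes and lists, the Runx1 share with hemogenic endothelial-like cells, the lists and seed sites without genes near called genes, and the arterial-like and venous-like lists and the genes adjusted over a list alone without 1 library were chosen after seeing the data. Of the values of called genes, Pf4 included, under the alternatives that tested them, 417 kept their direction and side of the threshold, 27 lost significance and 0 turned; for the lists called in the 4 classes these were 107, 79 and 4, and 78 shares stayed within 1 SD while 5 moved. The cause was not tested for any change below. Leaving out 1 library leaves its group with 1, assumed to vary like the other group.

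Without a filter on low counts 83 genes were called in endothelial-like cells, 36 in arterial-like, 35 in venous-like and 24 in hemogenic endothelial-like cells and 9 for the interaction, against 15, 4, 11, 3 and 1. DESeq2 called 40, 9, 9, 1 and 0 (26 unadjusted for the interaction). All 15 endothelial-like genes were called without the filter and by DESeq2. Sums thinned to equal depth gave 2 arterial-like genes, 7 venous-like genes and 0 for the interaction (488 unadjusted, edgeR). A mitochondrial limit of 20% gave 1 hemogenic endothelial-like gene and 0 for the interaction (464 unadjusted, edgeR), and keeping doublets gave 2 for the interaction. F630028O10Rik, Tagap, Zfp945 and Prss41 lost their call in endothelial-like cells with doublets kept, and Tagap and Prss41 with thinned sums. Leaving out 1 library in turn gave 18 to 64, 11 to 74, 13 to 48, 3 to 44 and 2 to 64 genes.

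The hemogenic endothelial-like difference ranged from 0.562 to 2.52 percentage points without 1 library. The Runx1 difference was -0.414 without thinning, 1.11 with hemogenic endothelial-like cells included, and -0.0665 to 0.197 without 1 library. Of the lists, 0 passed with an estimated correlation and 0 with fry in either class, 2 in hemogenic endothelial-like cells with doublets kept, and 5 to 8 (endothelial-like) and 5 to 11 (hemogenic endothelial-like) without 1 library. There, the hematopoietic progenitor list turned upward without WT replicate 2 (adjusted p = 0.469) or KO replicate 1 (0.823), and the interferon list without KO replicate 1 (0.847); their adjusted p ranged from 6.73e-13 to 0.823 and from 0.0118 to 0.847 without 1 library. In venous-like cells the G2 and M phase list turned downward without KO replicate 1 (0.711), with a range of 3.09e-12 to 0.711. The seed site test (limma's camera) turned upward against matched genes (adjusted p = 0.999), without WT replicate 2 (adjusted p = 0.142) and without KO replicate 1 (adjusted p = 0.635), with a range of 0.131 to 0.635 without 1 library.

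The replicate numbers are shared by the groups without a stated meaning. With the number as a replicate block, 28, 81, 36 and 30 genes were called in the 4 classes and 8 lists in endothelial-like cells. In hemogenic endothelial-like cells 7 lists passed, 3 of the 6 called without the block among them; hematopoietic progenitor (adjusted p = 0.283), interferon (0.272) and unfolded protein response (0.0516) did not. The hemogenic endothelial-like difference was 2.84 within number 1 and 0.242 within number 2. Deviations from the group means correlated between libraries of the same number (0.488 in endothelial-like cells). Splitting the libraries by number called 1031 genes against 15 for the genotype, which points to a structure of the samples, and the other split 0 (edgeR). No venous-like cluster earned its name at resolutions of 0.5 and 2, so venous-like genes and the interaction have no value there, nor do hemogenic endothelial-like genes and class shares at 0.5.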

Other observations

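Primordial germ cell-like cells, led by Dppa5a, Dppa3 and Pou5f1, are outside the endothelial comparisons. Gene tests in them and in cells like liver sinusoidal or lymphatic endothelium were not among the tests fixed beforehand. In the germ cell-like cells 13 of 10432 genes differed (edgeR). Wdfy1 rose by 2.48 on the log2 scale (SE 0.247), Fam81a by 2.52 (SE 0.272), Sbp by 3.32 (SE 0.542) and Phlda2, an imprinted regulator of placental growth, by 1.03 (SE 0.179, edgeR adjusted p = 0.0414). The G-protein subunit gene Gng13 fell by 3.83 (SE 0.422), the junction protein gene Cgnl1 by 2.81 (SE 0.273) and Mettl23 by 1.58 (SE 0.148). In cells like liver sinusoidal or lymphatic endothelium, 6 of 10604 genes differed (edgeR). Of these, Cacna1e rose by 4.45 (SE 0.563) and the glutamate receptor subunit gene Grin2c by 2.78 (SE 0.367). Of the 15 genes called in endothelial-like cells, 4 were also called in this class, and 3 in primordial germ cell-like cells.

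In erythroid-like and mesenchymal-like content, but not in megakaryocyte-like cells, libraries of the same replicate number lay closer together than libraries of the same genotype. Hbb-y, an embryonic globin, had 4862 CPM in WT replicate 1 and 4369 in KO replicate 1 over all barcodes, and 554 in WT replicate 2 and 765 in KO replicate 2. Erythroid-like cells were 2.05% and 1.70% of the libraries numbered 1, and 0.189% and 0.323% of those numbered 2. Afp, a yolk sac and liver gene, had 14.7 CPM in KO replicate 2, and 0.0315, 0.286 and 0.0273 in WT replicates 1 and 2 and KO replicate 1.

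Y-linked UMIs were seen in 84.0% of endothelial-like cells of KO replicate 1, and in 53.0%, 54.6% and 53.0% of those of WT replicates 1 and 2 and KO replicate 2.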
